A study of Homo sapiens with 6 samples.

How the data were processed

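Total RNA from MCF-7 cells was measured on Affymetrix whole human genome arrays, 1 array per replicate, after labelling of 5 µg of RNA with biotin. The 6 arrays came from 3 groups of 2 biological replicates: untreated cells, cells transfected with a control oligonucleotide (anti-control) and cells transfected with an oligonucleotide against miR-21 (anti-21), both at 50 nM and harvested after 24 h. Cells grew in medium with 10% serum. No group received the transfection reagent alone. The replicate numbers are not stated to pair the arrays of different groups, and array dates or batches are not given in the sources used here.

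The deposited values are on a log2 scale, 1 value per probe set and array, summarized by the authors with RMA per the submitters' processing notes. The version, the background step and the annotation behind RMA are not given in the sources used here. Every one of the 54675 probe sets had a value on all 6 arrays, and 62 of them are control probe sets of the manufacturer. The values were used as deposited, with no second normalization and no filter on dim probe sets. The distributions of the arrays were close but not identical. The median standard error of a group difference was 0.103 log2, and the median of the probe set means was 5.61.

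Gene symbols were taken from the platform table, in which 41097 probe sets carried 1 symbol, 1801 several and 11777 none. Of those with 1 symbol, 41043 matched the reference gene table by their gene number and 54 did not, and 0 symbols were changed by the match. Each gene was represented by the probe set with exactly 1 symbol and the highest mean over the 6 arrays, which left 19775 genes, 10523 of them with several probe sets to choose from. Probe sets with several symbols or none were left out of the gene tests, among them those shared by VMP1 and MIR21 and by PDCD4 and MIR4680, which were read among all probe sets.

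Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend). The model had 1 coefficient per group over all 6 arrays, so that 3 residual degrees of freedom and 6.75 prior degrees of freedom stood behind each two-sided moderated test. P-values were adjusted over the 19775 genes by the method of Benjamini and Hochberg with a threshold of 0.05 in each of 3 comparisons: anti-21 against anti-control, anti-control against untreated and anti-21 against untreated. A second count took genes past the threshold with an absolute log2 difference of at least 1. Each pair of comparisons shares the 2 arrays of 1 group, so the comparisons are not independent.

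The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. By that rule, the genes named in each comparison are the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap. From each list it takes up to 4 members with the smallest p, and it adds VMP1, PDCD4, TPM1, PTEN, RECK, SPRY1, SPRY2, BTG2, TIMP3 and SERPINB5 in every comparison. ADM, KDM3A, ENO2, VEGFA and the 5 glycolytic enzyme genes at the low end of the hypoxia list were named between the oligonucleotides after their values were seen.

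The 22 lists covered reported miR-21 targets, the miRNA pathway with the miR-21 host gene, and 6 stress and signalling responses (interferon, unfolded protein and amino acid stress, heat shock, hypoxia and glycolysis, oxidative stress with metallothioneins, TGF-beta and SMAD). Others held NF-kappaB and inflammatory genes, immediate early genes, estrogen-responsive genes, p53 targets, apoptosis regulators, mitosis, DNA replication, histones, ribosomal proteins with translation factors, cholesterol synthesis, and lysosome with autophagy. A further 3 held cell markers: luminal epithelial, mesenchymal with fibroblast and basal, and blood with endothelial. Each was tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also takes its degrees of freedom from the residuals (3 here), so a lost call need not come from the correlation. The estimate was 0.010 for reported miR-21 targets, the preset value, and 0.480 for hypoxia and glycolysis. Members past the threshold were counted with adjustment over all genes and over the list alone. The overlap of the comparisons with untreated cells was set against 50 simulations of unchanged groups that share the untreated arrays. The search for miR-21 seed matches that had been planned was not run, since no 3′ UTR sequence was at hand.

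The test was tried on simulated data of the same size, with 200 changed genes per comparison. Values were drawn for each gene on its own from a normal distribution with its moderated variance. Recovery in the data may be lower, where VMP1 at 1.30 log2 between the oligonucleotides was not past the threshold. Changes of 1 and 2 log2 were recovered in 100.0% of cases in each comparison. Changes of 0.5 were recovered in 67.2% for anti-21 against anti-control, 74.3% for anti-control against untreated and 72.0% for anti-21 against untreated, with 13, 10 and 23 unchanged genes called. On simulated values the list test called 0 of 22 lists without a shift and 1, the shifted one, after a shift of 0.3. The simulated genes were independent of one another, so this does not show how often camera calls unshifted lists of correlated genes.

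Alternatives tried were an intensity trend or a robust fit in eBayes, only the arrays of the groups compared, and the replicate number as a block. Others were quantile, median and cyclic loess scaling on top of the deposited values, only genes above the median of all probe set means, and other choices of probe set: the mean of all, every one tested, and without those marked _s_at, _x_at or _a_at as shared. Each of the 6 arrays was also left out in turn. Added after the data were seen were the assignment of probe sets shared with small RNA genes to their host gene, the replicate block with the anti-control numbers exchanged, and a fit without the arrays of anti-control replicate 2 and anti-21 replicate 2.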

Results

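Gene expression was profiled in MCF-7, an established breast cancer cell line of luminal epithelial type that responds to estrogen. Cells were untreated or taken 24 h after lipid transfection of 50 nM of an oligonucleotide against miR-21 (anti-21) or of a control oligonucleotide (anti-control). miR-21 is a microRNA that lowers the output of its target messages, so the question was which messages differ once it is blocked. Each of the 3 groups had 2 biological replicates, and each replicate was hybridized to 1 Affymetrix whole-genome array, 6 arrays in all. Every array gave a value for each of 54675 probe sets, with array medians between 5.58 and 5.63 on the log2 scale, and 19775 genes were tested. The untreated arrays lay at 21.60 and 23.33 on the first principal component, which held 53.4% of the variance. The 4 transfected arrays lay between -15.14 and -7.72. The standard deviation of the difference between replicate arrays was 0.171 log2 for untreated cells, 0.204 for anti-control and 0.226 for anti-21. Between an anti-21 and an anti-control array it was 0.223 to 0.236, near that of the anti-21 replicates. The array of anti-control replicate 2 had a mean of 6.47 on the poly-A spike-in probe sets, against 7.27 to 7.89 on the other 5 arrays. Its 3′ minus 5′ difference for actin was 0.12, against 0.26 to 0.35. The array of anti-21 replicate 2 had a mean of 8.72 on the 18S ribosomal RNA probe sets, against 6.64 to 7.58 on the others.

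The knockdown targets mature miR-21, which these arrays do not measure. miR-21 is encoded within VMP1, a gene of autophagy, and is also made from a primary transcript of its own, so probe sets annotated to both genes may read either. The probe set annotated to VMP1 alone had means of 10.04 ± 0.02 (SD, n = 2) in untreated cells, 9.23 ± 0.22 with anti-control and 10.53 ± 0.63 with anti-21. Anti-21 minus anti-control was 1.30 ± 0.23 log2 (SE, 2.46-fold, adjusted p = 0.109). Another 3 probe sets are annotated to both VMP1 and MIR21. The middle one in brightness read 11.97 and 11.82 in untreated cells, 11.26 and 11.27 with anti-control, and 11.81 and 12.10 with anti-21. Its difference between the oligonucleotides was 0.69 ± 0.12 (adjusted p = 0.173 among all probe sets), and with anti-control it fell by 0.63 against untreated cells (adjusted p = 0.0341). The dimmest read 7.10 and 7.25, 6.68 and 6.58, and 7.01 and 7.61 in the same order, a difference between the oligonucleotides of 0.68 ± 0.18 (adjusted p = 0.334). The brightest read between 12.32 and 12.39 on all 6 arrays, with a difference of 0.02 ± 0.09. VMP1 passed the threshold between the oligonucleotides without the array of anti-21 replicate 1 (1.74, adjusted p = 0.0096). Without anti-21 replicate 2 it was at 0.86 ± 0.15 (adjusted p = 0.110). Against untreated cells VMP1 was at -0.81 with anti-control (adjusted p = 0.0636). This fall was past the threshold with only the 2 groups compared (0.0048), with an intensity trend (0.0308), the replicate number as a block (0.0243), dim genes left out (0.0450) and both arrays with unusual control signals left out (0.0203). With anti-21 VMP1 was at 0.49 (adjusted p = 0.242), or 0.94 (adjusted p = 0.0101) without anti-21 replicate 1 and 0.05 (adjusted p = 0.895) without anti-21 replicate 2. The difference from untreated cells thus rests on the array with high 18S signals, with 10.09 and 10.98 on the anti-21 arrays against 10.05 and 10.03 on the untreated ones.

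PDCD4, a repressor of translation and a reported target of miR-21, has 1 dim probe set of its own, which entered the gene test. It was at -0.09 ± 0.13 for anti-21 minus anti-control and at 0.19 and 0.10 for anti-control and anti-21 against untreated cells (adjusted p between 0.412 and 0.890). Another 4 bright probe sets are shared with the microRNA gene MIR4680, and their signs were the opposite. All 4 fell with anti-control, with differences from untreated cells of -1.06 to -0.92 log2 (adjusted p between 0.0062 and 0.0091 among all probe sets). With anti-21 they were at -0.77 to -0.53 (adjusted p between 0.0152 and 0.0699). Between the oligonucleotides they were higher with anti-21 by 0.28 ± 0.12 to 0.50 ± 0.14, none past the threshold (adjusted p between 0.355 and 0.569). Of the other targets fixed by name, anti-21 minus anti-control was 0.30 ± 0.14 for SPRY1, 0.08 ± 0.13 for SERPINB5 and -0.06 ± 0.09 for SPRY2. It was -0.06 ± 0.14 for RECK, -0.11 ± 0.14 for TIMP3 and -0.19 ± 0.13 for TPM1, and none of the 6 passed (adjusted p between 0.568 and 0.940). SPRY1 was at 0.11 without anti-21 replicate 1 and 0.50 without anti-21 replicate 2, and TIMP3 ranged from -0.17 to -0.04 without each array. The sign of these small differences turned without anti-control replicate 1 for TPM1 (0.01) and SPRY2 (0.01). It also turned without anti-control replicate 2 for RECK (0.19) and without anti-21 replicate 1 for SERPINB5 (-0.03). PTEN and BTG2 had no probe set with a single symbol and were not analysed here. TIMP3, an inhibitor of metalloproteinases, fell by 0.62 with anti-control against untreated cells (adjusted p = 0.0291). That call was lost without anti-control replicate 1 (adjusted p = 0.0988), anti-control replicate 2 (0.129) or untreated replicate 1 (-0.39, 0.166). With anti-21 TIMP3 fell by 0.73 (adjusted p = 0.0140), a call lost without anti-21 replicate 2 (0.0793) or untreated replicate 1 (0.0798).

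**Figure D1:**
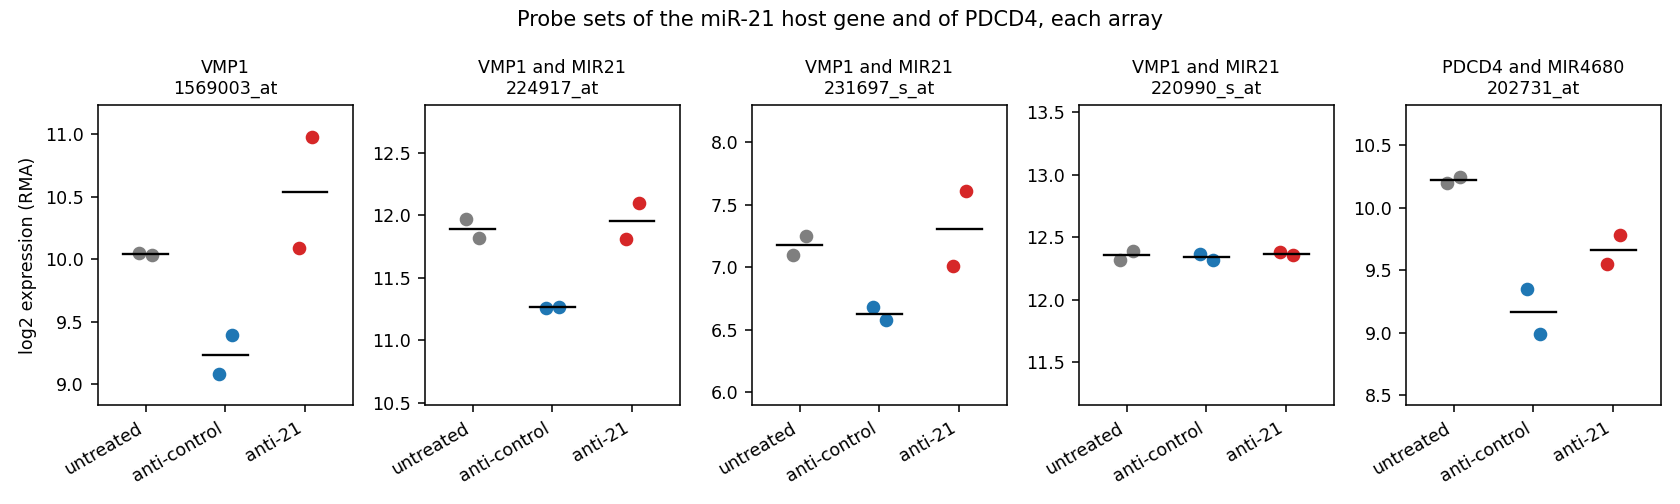
Log2 expression on each array (dots) and group means (lines) of the probe set of VMP1, the 3 probe sets shared by VMP1 and MIR21, and 1 of the 4 probe sets shared by PDCD4 and MIR4680, for untreated, anti-control and anti-21 cells (n = 2 each). The VMP1 probe set averaged 10.04, 9.23 and 10.53 in that order, while the brightest of the shared probe sets stayed between 12.32 and 12.39.

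With anti-21 against anti-control, 19 of 19775 genes changed, 11 higher and 8 lower. The rise was largest for ANKRD37, a gene induced by low oxygen, which went from 10.17 ± 0.21 to 11.37 ± 0.18 (SD, n = 2 each). That is a 2.29-fold rise (1.19 ± 0.13 log2, SE, adjusted p = 0.0322). With the mean of its 2 probe sets, the other being dim, ANKRD37 was at 0.47 (adjusted p = 0.272), no longer past the threshold and below POFUT4 (0.75), PDK1 (0.65) and TOP6BL (0.58). Other genes tied to low oxygen and sugar use rose with it. PDK1, a kinase that restrains pyruvate dehydrogenase, rose 1.86-fold (adjusted p = 0.0469), and PFKFB4, an enzyme that sets the pace of glycolysis, 1.64-fold (adjusted p = 0.0322). ANGPTL4, an inhibitor of lipoprotein lipase, rose 1.78-fold (adjusted p = 0.0411), and MIR210HG, the host transcript of miR-210, 1.92-fold (adjusted p = 0.0385). The transcription factor gene FOS rose 1.70-fold (adjusted p = 0.0330), and CREBRF, TOP6BL, DLEU2, PPFIA4 and POFUT4 rose 1.66- to 2.08-fold. The DLEU2 probe set is marked as shared, and the gene was at 0.09 (adjusted p = 0.845) without such probe sets and at 0.35 with the mean of its 7 probe sets. With that mean CREBRF was at 0.50 instead of 1.00 and TOP6BL at 0.58 instead of 1.05, and the calls of DLEU2, CREBRF, TOP6BL, POFUT4, PDK1 and PFKFB4 were lost (adjusted p between 0.0594 and 0.327). CXCL8, the gene of the neutrophil chemokine interleukin-8, fell by 1.18 ± 0.17 log2 (adjusted p = 0.0469), from 5.73 ± 0.38 to 4.54 ± 0.09, levels near or under the median probe set of 5.61. The drug efflux pump gene ABCG2 (-0.78 ± 0.09) and the sphingosine-1-phosphate receptor gene S1PR3 (-0.79 ± 0.10) fell. So did the protocadherin genes PCDH9 (-0.98 ± 0.14) and PCDH19 (-0.76 ± 0.09), and KBTBD8, STON2 and PWWP3B (-1.06 to -0.90). PCDH9 was read on a probe set marked as shared, and was at -0.23 (adjusted p = 0.605) without such probe sets and at -0.31 (adjusted p = 0.275) with the mean of its 4 probe sets. CXCL8, ANGPTL4 and PPFIA4 were read on marked probe sets too, and PPFIA4 has no other. Without marked probe sets only 16 of the 19 genes could be measured, and 14 kept their call. With the mean of probe sets STON2 was at -0.42 and its call was lost (adjusted p = 0.137). The calls of S1PR3 (-0.80, adjusted p = 0.0660) and PWWP3B (-0.90, adjusted p = 0.0583) were lost at values that stayed as large. PWWP3B has 1 probe set, so only the adjustment and the spread shared across genes changed for it.

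Several of these 19 genes had moved the other way with anti-control against untreated cells. CXCL8 rose by 1.24 with anti-control (adjusted p = 0.0028) and was at 0.06 with anti-21. ABCG2 rose by 0.61 (adjusted p = 0.0045) and was at -0.18 with anti-21. CREBRF, a regulator of the unfolded protein response, fell by 1.41 (adjusted p = 5.44e-04) and was at -0.41. PDK1 differed from untreated cells by -0.10 with anti-control and rose by 0.80 with anti-21 (adjusted p = 0.0059, or 0.0597 without untreated replicate 2). FOS was at 0.17 and rose by 0.93 (adjusted p = 5.83e-04), while ANKRD37 rose with both, by 1.52 and 2.71. The anti-control arrays enter both differences with opposite signs, so moves in opposite directions are in part built in.

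Hypoxia and glycolysis genes were higher as a group with anti-21 than with anti-control. All 32 measured members had a positive difference, also after each of 3 other scalings, with a median of 0.450 log2 (1.37-fold). Among all genes tested 4 of the 32 rose (ANKRD37, PDK1, ANGPTL4 and PFKFB4), and 23 rose adjusted over the list alone. The 28 members not past the threshold among all genes included ADM (0.93 ± 0.19), KDM3A (0.80 ± 0.13), ENO2 (0.77 ± 0.13) and VEGFA, a main signal for vessel growth (0.58 ± 0.12). The abundant glycolytic enzyme genes ENO1, GAPDH, PGAM1, ALDOA and TPI1 were at 0.03 to 0.08. The list was past the threshold with camera at the preset correlation (adjusted p = 1.91e-28) and not otherwise (adjusted p = 0.522 with an estimated correlation, 0.318 with fry). Array means of the list were 10.42 and 10.33 in untreated cells, 10.66 and 10.42 with anti-control and 11.04 and 10.97 with anti-21. The lower anti-control value belongs to replicate 2, the array with low poly-A spike-in signals, and without it the median was 0.272.

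**Figure D2:**
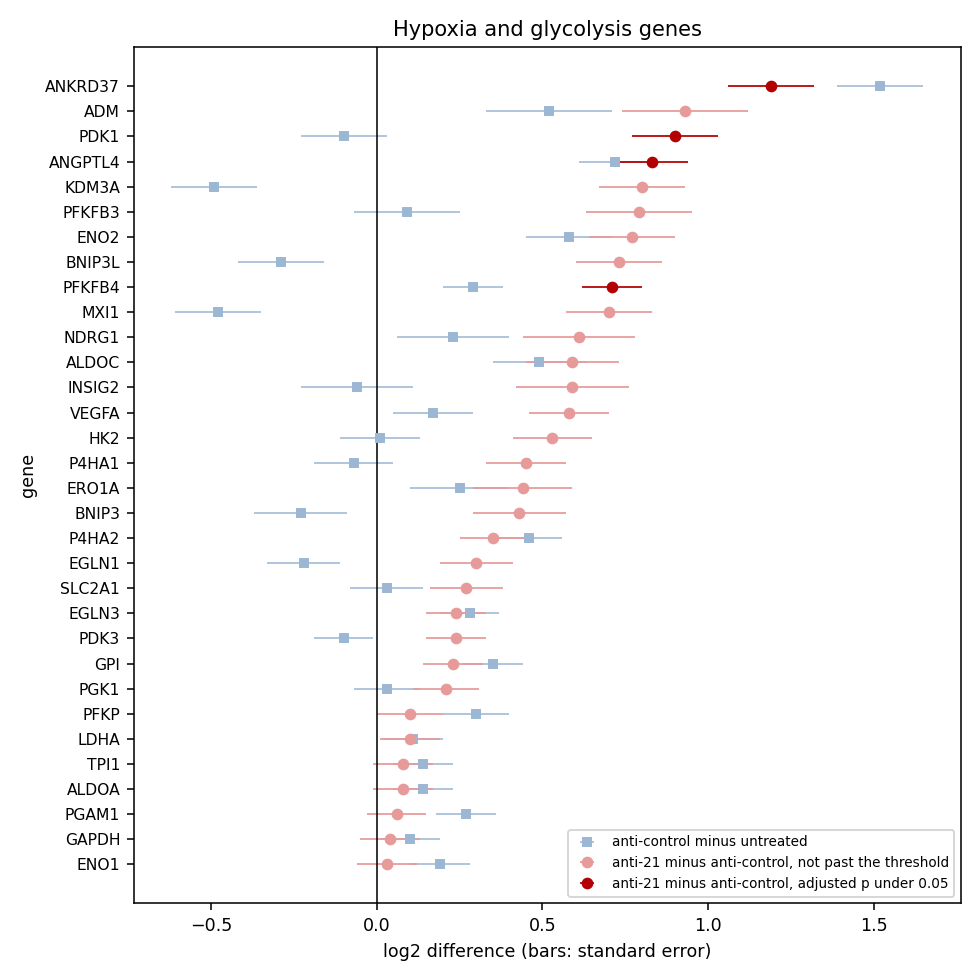
Log2 difference of each of the 32 hypoxia and glycolysis genes (bars, SE, n = 2 per group), anti-21 minus anti-control (circles, dark where the adjusted p was under 0.05) and anti-control minus untreated (squares). Circles lie between 0.03 (ENO1) and 1.19 (ANKRD37), and 4 of them were past the threshold.

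Reported miR-21 targets were slightly higher with anti-21 than with anti-control. Of 84 measured targets 51 had a positive difference, with a median of 0.057 log2 (1.04-fold), and 0 rose or fell, either among all genes or adjusted over the list alone. The members with the smallest p were LRRFIP1 (0.45 ± 0.09, adjusted p = 0.158), RP2 (0.46 ± 0.11), GLCCI1 (0.42 ± 0.13) and APAF1, the core of the apoptosome (0.39 ± 0.13). The probe sets read for LRRFIP1 (1 of its 9) and APAF1 (1 of its 3) are marked as shared. Without anti-control replicate 2 GLCCI1 was at 0.21 and APAF1 at 0.22. Camera with an estimated correlation gave the list an adjusted p = 0.522. The estimate was 0.010, the preset value, so this comes from the fewer degrees of freedom and not from the correlation. At the preset correlation the list was past the threshold (adjusted p = 0.0148). That call was lost without anti-control replicate 2 (median 0.040, adjusted p = 0.240) or anti-21 replicate 2 (0.051, adjusted p = 0.170). It was also lost with the mean of all probe sets of a gene (0.025, adjusted p = 0.361) and without probe sets marked as shared (adjusted p = 0.108), and without anti-21 replicate 1 the median was 0.031 (adjusted p = 0.0183).

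Oxidative stress and metallothionein genes were lower with anti-21 than with anti-control, at a median of -0.132 log2 with 5 of 28 members positive (adjusted p = 1.48e-05; adjusted p = 0.593 with an estimated correlation). Among all genes 0 of them fell, and 10 fell adjusted over the list alone, with AKR1C3 at -0.44 ± 0.10, AKR1B10 at -0.44 ± 0.10 and SRXN1 at -0.43 ± 0.09. Without anti-control replicate 1 the median was -0.204. Heat shock genes were also lower, at a median of -0.123 with 5 of 21 members positive (adjusted p = 0.0065; adjusted p = 0.522 with an estimated correlation). None was past the threshold, adjusted over the list alone included, with HSPH1 at -0.27 ± 0.10 (-0.39 to -0.15 without each array) and DNAJB1 at -0.24 ± 0.09. That call was lost without anti-control replicate 1 (-0.076, adjusted p = 0.156) or anti-21 replicate 1 (-0.096, adjusted p = 0.0925). Against untreated cells the oxidative stress list had medians of 0.332 with anti-control and 0.258 with anti-21, and the heat shock list 0.201 and 0.155. By their medians both lists thus rose less with anti-21 and were not below untreated cells. The anti-control arrays enter both differences with opposite signs here too. The other 18 lists were not past the threshold in this comparison (adjusted p between 0.181 and 0.966), and fry called 0 of the 22.

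Of the 19 genes changed between the oligonucleotides, 6 changed by at least 2-fold, and 1812 genes were at an unadjusted p under 0.05, where 989 would be given by chance. The limma count was 0 without anti-control replicate 1 (2632 unadjusted), anti-control replicate 2 (1565), untreated replicate 1 (1528) or untreated replicate 2 (1528). Leaving out an array of the third group equals the fit of only the 2 groups compared, since the lone array left there adds nothing to the estimate of spread. The loss of calls without an untreated array is thus one of the third group's share in that estimate. The count was 2 without anti-21 replicate 1 and 15 without anti-21 replicate 2, of which 1 and 6 were among the 19, and the 19 genes kept their direction each time. After centring on array medians 13 of the 19 were left, the calls of CXCL8 (adjusted p = 0.0639), ANGPTL4 (0.0531), PDK1 (0.0639), CREBRF (0.0682), PCDH9 (0.0608) and STON2 (0.0571) being lost. Cyclic loess ended those of CXCL8 (0.0587) and PCDH9 (0.0563).

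Between anti-control and untreated cells 1509 genes differed, 441 higher and 1068 lower with anti-control, 106 of them by at least 2-fold. Without a group given the reagent alone, these differences cannot be assigned to the oligonucleotide. IFIT1, an antiviral protein induced by interferon, rose 7.82-fold (2.97 ± 0.22 log2, SE, adjusted p = 1.09e-04), from 5.97 ± 0.50 to 8.94 ± 0.27 (SD, n = 2 each). HMOX1, the heme-degrading enzyme of the oxidative stress response, rose 6.26-fold (2.65 ± 0.09, adjusted p = 1.09e-06). The aldo-keto reductase genes AKR1C1, AKR1C2 and AKR1C3 rose 6.26- to 6.95-fold, and AKR1B10 rose 4.44-fold. The cystine transporter gene SLC7A11 rose 4.33-fold and the smooth muscle actin gene ACTG2 4.64-fold. The sequences of the AKR1C genes are close to one another, and AKR1C2 was at 0.27 on its dim probe set that is not marked as shared. SELENOP, whose protein carries selenium in plasma, fell from 6.72 ± 0.09 to 3.72 ± 0.09 (adjusted p = 1.09e-06). The lower level is under the lower quartile of the anti-control arrays (4.12 and 4.16), so the size of this fall is a lower bound. The transporter gene ABCC11 (-2.68 ± 0.18), the adaptor gene BLNK (-2.67 ± 0.16) and MSMB (-2.19 ± 0.14) fell as well, and so did HSD17B11, TNFSF15, PTGER4, ABHD2, ITPR1 and YPEL3 (-2.12 to -1.74). For SELENOP and ABCC11 these are the brightest probe sets, and the dimmer ones not marked as shared were at -0.23 and 0.16 for SELENOP and -0.21 for ABCC11.

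Interferon response genes rose with anti-control. Of 59 measured, 22 rose and 0 fell (32 and 0 adjusted over the list alone), with IFI27 at 1.92 ± 0.10 and OAS1 at 1.56 ± 0.12. IFIT3 rose from 4.12 to 6.54, a lower bound on its rise since the untreated level is near the lower quartile of those arrays (4.10 and 4.09). Of 28 oxidative stress and metallothionein genes 14 rose and 1 fell (16 and 2 adjusted over the list alone). Genes of the unfolded protein and amino acid stress response rose in 12 of 36 cases with 1 fall (19 and 3 adjusted over the list alone). Among them were the serine synthesis genes PHGDH (0.69 ± 0.09) and PSAT1 (0.78 ± 0.12) and the stress gene TRIB3 (0.64 ± 0.09). Of 21 heat shock genes 5 rose (10 adjusted over the list alone), with the chaperone genes HSPH1 at 0.56 ± 0.10 and DNAJB1 at 0.51 ± 0.09. The preset correlation gave these 4 lists an adjusted p of 6.51e-16, 7.86e-10, 2.20e-06 and 1.73e-04 in that order. Each of the 4 had an adjusted p = 0.154 with an estimated correlation. Fry gave them an adjusted p of 0.0102, 0.0046, 0.0118 and 0.0195 in the same order.

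Hypoxia and glycolysis genes had a smaller shift with anti-control, at a median of 0.144 (adjusted p = 0.0123; adjusted p = 0.644 with an estimated correlation). Of 32 measured, 4 rose and 1 fell (10 and 2 adjusted over the list alone), with ANKRD37 at 1.52 ± 0.13 and ANGPTL4 at 0.72 ± 0.11. Without anti-control replicate 1 the median was 0.047 (adjusted p = 0.725) and without untreated replicate 2 it was 0.112 (adjusted p = 0.0854). Without anti-control replicate 2, the array with low poly-A spike-in signals, it was 0.227 (adjusted p = 2.32e-06). Mitosis genes were higher at a median of 0.145 (adjusted p = 0.0028; adjusted p = 0.546 with an estimated correlation). Of 42 measured, 3 rose and 0 fell (9 and 1 adjusted over the list alone), the anaphase activator gene CDC20 among them (0.50 ± 0.09). The call of this list was lost without anti-control replicate 1 (median 0.085, adjusted p = 0.108) or untreated replicate 1 (0.103, adjusted p = 0.0988).

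Estrogen-responsive genes fell with anti-control. Of 38 measured, 15 fell and 0 rose (21 and 0 adjusted over the list alone), with the progesterone receptor gene PGR at -1.30 ± 0.09, PDZK1 at -1.23 ± 0.13, MYB at -1.09 ± 0.09 and the survival gene BCL2 at -1.08 ± 0.10. Of 23 TGF-beta and SMAD response genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), with the decoy receptor gene BAMBI at -0.91 ± 0.09 and the ligand gene TGFB2 at -0.80 ± 0.12. Of 16 genes in the miRNA pathway list 4 fell (5 adjusted over the list alone). Among them were the Argonaute gene AGO4 (-0.74 ± 0.11) and TNRC6C (-0.64 ± 0.09). With the mean of their probe sets AGO4 was at -0.26 (adjusted p = 0.0918) and TNRC6C at 0.05, and both calls were lost. The preset correlation gave these 3 lists an adjusted p of 2.14e-13, 1.50e-04 and 0.0083, and each had an adjusted p = 0.154 with an estimated correlation. Fry gave them 0.0046, 0.0167 and 0.0614, the last not past the threshold. Luminal epithelial markers had a median of -0.118 (adjusted p = 0.0113; adjusted p = 0.154 with an estimated correlation). That call was lost with dim genes left out (adjusted p = 0.0631) and without probe sets marked as shared (-0.127, adjusted p = 0.167). The 1 member of 19 past the threshold, the tight junction gene CLDN4, nevertheless rose (0.35 ± 0.09), and 0 members passed adjusted over the list alone.

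Reported miR-21 targets were also lower with anti-control, at a median of -0.041 (adjusted p = 0.0182; adjusted p = 0.187 with an estimated correlation). Of 84 measured, 14 fell and 1 rose (17 and 6 adjusted over the list alone), with SASH1 at -0.76 ± 0.10. With the mean of all probe sets of a gene the median was 0.000 and the call was lost (adjusted p = 0.0735). The call was also lost with dim genes left out (-0.088, adjusted p = 0.0631) and without anti-control replicate 2 (adjusted p = 0.0756). Replication-dependent histone genes, whose sequences are close to one another, fell in 5 of 13 cases (7 falls and 1 rise adjusted over the list alone), with H4C8 at -1.15 ± 0.14 and H2AC8 at -1.01 ± 0.11. Their median was -0.293 (adjusted p = 0.0037; adjusted p = 0.187 with an estimated correlation), or -0.195 without anti-control replicate 2. Without probe sets marked as shared it was -0.006 and the call was lost (adjusted p = 0.0866). Ribosomal protein and translation factor genes had a median of -0.082 (adjusted p = 0.0417; adjusted p = 0.269 with an estimated correlation). Of 20 measured, 2 fell (2 falls and 2 rises adjusted over the list alone), the initiation factor gene EIF4B among them (-0.66 ± 0.10). This list's call was lost without any 1 of the 4 arrays compared (adjusted p between 0.0502 and 0.0988), with only the 2 groups compared (0.0530), with dim genes left out (0.178) and without probe sets marked as shared (-0.023, adjusted p = 0.192).

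**Figure D3:**
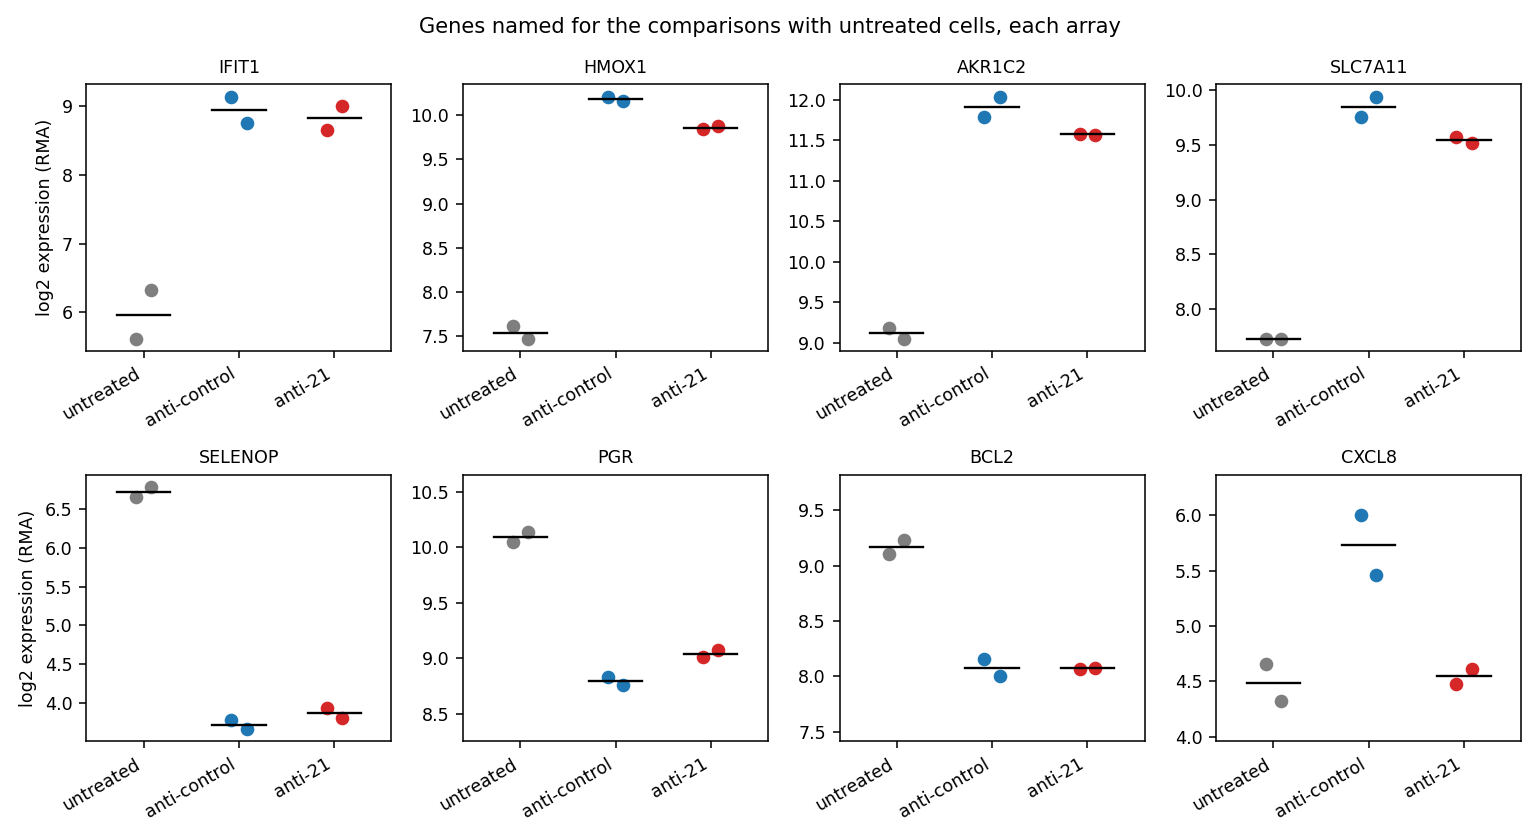
Log2 expression on each array (dots) and group means (lines) of 8 genes in untreated, anti-control and anti-21 cells (n = 2 each): IFIT1, HMOX1, AKR1C2 and SLC7A11, which rose with both oligonucleotides, SELENOP, PGR and BCL2, which fell with both, and CXCL8. The mean of IFIT1 went from 5.97 in untreated cells to 8.94 and 8.82, and CXCL8 went from 4.49 to 5.73 with anti-control and was at 4.54 with anti-21.

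For anti-control against untreated cells 4626 genes were at an unadjusted p under 0.05. The limma count past the adjusted threshold was 535 without anti-control replicate 2, 494 without untreated replicate 1 and 420 without untreated replicate 2. Without anti-control replicate 2 the calls of DNAJB1 (adjusted p = 0.0631), CDC20 (0.0710) and TGFB2 (0.0536) were lost. Those of DNAJB1 (0.0823), CDC20 (0.0959), HSPH1 (0.0924) and EIF4B (0.0518) were lost without untreated replicate 1. Those of DNAJB1 (0.0640), CDC20 (0.0626), HSPH1 (0.0652) and ANGPTL4 (0.0564) were lost without untreated replicate 2, and that of CLDN4 without each of the 4 arrays compared (0.0882 to 0.208). The call of CLDN4 was also lost with only the 2 groups compared (0.0631) and with the mean of probe sets (0.109).

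With anti-21 against untreated cells, 1425 genes changed, 422 higher and 1003 lower, 131 of them by at least 2-fold. IFIT1 rose 7.22-fold (2.85 ± 0.22 log2, SE, n = 2 each, adjusted p = 9.62e-05) and ANKRD37 6.54-fold (2.71 ± 0.13, adjusted p = 9.48e-06). IFIT3 rose from 4.12 to 6.54, again a lower bound. HMOX1 rose 4.99-fold, and AKR1C1, AKR1C2 and AKR1C3 4.61- to 5.50-fold. IFI27 rose 3.89-fold, ACTG2 3.54-fold and SLC7A11 3.51-fold. ABCC11 (-2.90 ± 0.18) and SELENOP (-2.84 ± 0.10) fell on their brightest probe sets, SELENOP to 3.87, again under the lower quartile (4.14), so that its fall is a lower bound. Their probe sets not marked as shared were at -0.15 for ABCC11 and at 0.05 and 0.11 for SELENOP, and that of AKR1C2 was at 0.11. TNFSF15, BLNK, HSD17B11, MSMB, PTGER4, ITPR1, ABHD2 and the steroid-conjugating enzyme gene UGT2B17 fell too (-2.42 to -1.85).

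Hypoxia and glycolysis genes rose with anti-21 against untreated cells in 16 of 32 cases with 0 falls (25 and 0 adjusted over the list alone), at a median of 0.483. Among them were ANGPTL4 (1.55 ± 0.11), the enolase gene ENO2 (1.35 ± 0.13) and PFKFB4 (1.00 ± 0.09). Interferon response genes rose in 23 of 59 cases with 0 falls (34 and 0 adjusted over the list alone), with OAS1 at 1.61 ± 0.12. Oxidative stress and metallothionein genes rose in 11 of 28 with 2 falls (15 and 3 adjusted over the list alone). Genes of the unfolded protein and amino acid stress response rose in 10 of 36 with 1 fall (14 and 3 adjusted over the list alone), with DDIT4 at 1.04 ± 0.10 and PHGDH at 0.91 ± 0.09. The preset correlation gave these 4 lists an adjusted p of 3.55e-19, 6.04e-16, 7.76e-08 and 6.97e-06 in that order. Each of the 4 had an adjusted p = 0.209 with an estimated correlation. Fry gave them an adjusted p of 0.0248, 0.0136, 0.0101 and 0.0156 in the same order.

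Immediate early genes had a median of 0.128 (adjusted p = 0.0260; adjusted p = 0.420 with an estimated correlation). Of 27 measured, 3 rose and 1 fell (6 and 1 adjusted over the list alone), FOS among the rises (0.93 ± 0.10). The list's call was lost without anti-21 replicate 2 (0.140), untreated replicate 2 (0.0619) or the probe sets marked as shared (0.0796). Mitosis genes had a median of 0.142 (adjusted p = 4.85e-04; adjusted p = 0.420 with an estimated correlation), a call lost without untreated replicate 1 (0.096, adjusted p = 0.0593). The 1 of 42 that rose was the cyclin gene CCNA2 (0.39 ± 0.09), and 0 rose adjusted over the list alone. Heat shock genes had a median of 0.155 (adjusted p = 0.0348; adjusted p = 0.353 with an estimated correlation). None of the 21 was past the threshold, and 2 rose and 2 fell adjusted over the list alone. That call was lost without untreated replicate 1 (0.216), the probe sets marked as shared (0.169) or anti-21 replicate 2, the array with high 18S ribosomal RNA signals (0.150).

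Estrogen-responsive genes fell with anti-21 in 18 of 38 cases with 0 rises (24 falls and 1 rise adjusted over the list alone), at a median of -0.367 (adjusted p = 1.42e-13; adjusted p = 0.155 with an estimated correlation). PDZK1 was at -1.76 ± 0.13, the adenosine receptor gene ADORA1 at -1.23 ± 0.10 and PGR at -1.05 ± 0.09. TGF-beta and SMAD response genes fell in 5 of 23 cases with 1 rise (5 and 1 adjusted over the list alone), with TGFB2 at -1.02 ± 0.12 and BAMBI at -0.79 ± 0.09. Their median was -0.140 (adjusted p = 0.0056; adjusted p = 0.209 with an estimated correlation), or -0.076 without anti-21 replicate 1. Of 16 genes in the miRNA pathway list 2 fell (4 adjusted over the list alone), TNRC6C among them (-0.94 ± 0.09, and -0.15 with the mean of its probe sets). The list had an adjusted p of 0.0173 (adjusted p = 0.209 with an estimated correlation), or 0.209 at the preset one without anti-21 replicate 1. Luminal epithelial markers fell in 3 of 19 cases (4 adjusted over the list alone), the pioneer factor gene FOXA1 among them (-0.44 ± 0.09). Their median was -0.148 (adjusted p = 0.0273; adjusted p = 0.209 with an estimated correlation), a call lost without anti-21 replicate 1 (-0.061, adjusted p = 0.117) or untreated replicate 1 (0.0593). It was also lost with dim genes left out (0.118) and without probe sets marked as shared (-0.076, adjusted p = 0.169).

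Histone genes fell with anti-21 in 5 of 13 cases (5 adjusted over the list alone), with H4C8 at -1.12 ± 0.14 and H2AC6 at -0.76 ± 0.11. Their median was -0.050 (adjusted p = 0.0398; adjusted p = 0.366 with an estimated correlation). It was -0.080 (0.133) without anti-21 replicate 1, -0.093 (0.0158) without anti-21 replicate 2, -0.002 (0.0911) without untreated replicate 1 and -0.099 (0.0250) without untreated replicate 2. The call was also lost after centring on array medians (-0.082, adjusted p = 0.0518) and without probe sets marked as shared (adjusted p = 0.169). Reported miR-21 targets were not past the threshold (adjusted p = 0.555), and the signs of their median (0.016), mean (-0.035) and test (down) differed. Of 84 measured, 6 rose and 5 fell (6 and 8 adjusted over the list alone), SASH1 among the falls (-0.70 ± 0.10).

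For anti-21 against untreated cells 4420 genes were at an unadjusted p under 0.05. The limma count past the adjusted threshold was 701 without anti-21 replicate 1, 737 without anti-21 replicate 2, 642 without untreated replicate 1 and 449 without untreated replicate 2. In that order the calls of FOXA1 (adjusted p = 0.0712, 0.115, 0.0780 and 0.171) and CCNA2 (0.125, 0.123, 0.186 and 0.118) were lost, as they were with the mean of probe sets (0.204 and 0.0529).

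**Figure D4:**
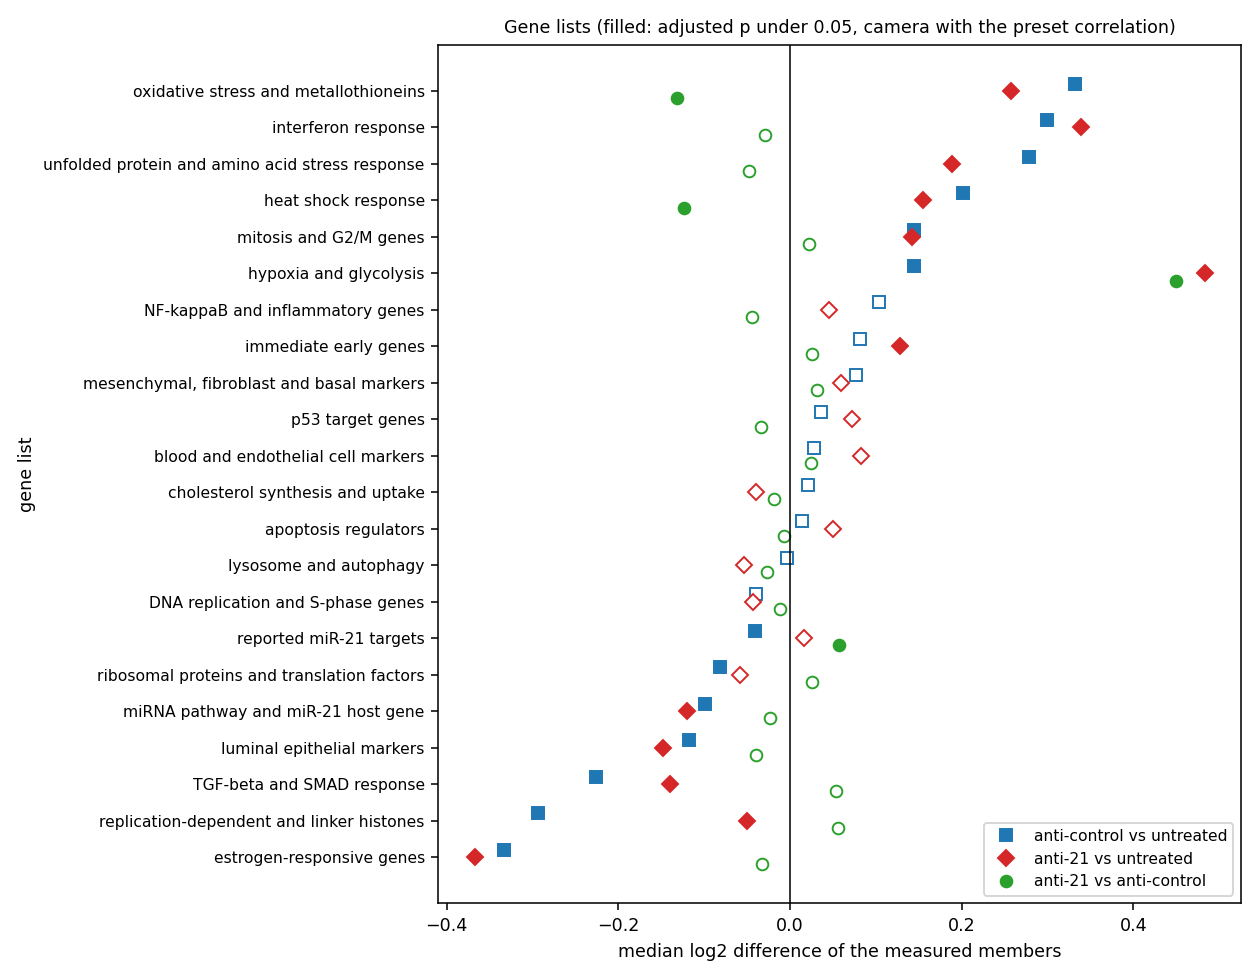
Median log2 difference of the measured members of each of the 22 gene lists (y axis) in the 3 comparisons: anti-control against untreated (squares), anti-21 against untreated (diamonds) and anti-21 against anti-control (circles), n = 2 arrays per group, filled where the camera test with the preset correlation gave an adjusted p under 0.05. The hypoxia and glycolysis list had medians of 0.144, 0.483 and 0.450 in that order, and the interferon list 0.299, 0.339 and -0.029.

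The genes that differed from untreated cells with the 2 oligonucleotides overlapped. In all, 185 were higher with both and 682 lower with both, and 1 was past the threshold in opposite directions. Independent lists of these sizes would share 9.41 and 54.2. IFIT1, HMOX1 and SLC7A11 were among the shared rises, and SELENOP, PGR and BCL2 among the shared falls. Both comparisons use the same 2 untreated arrays, which by itself raises the overlap and the correlation. In 50 simulations of unchanged groups against the same untreated arrays the shared counts averaged 0.02 and 0.06. Almost no gene is called in unchanged groups, so these counts do not show how far the shared arrays raise the overlap of long lists. The correlation of the log2 differences across genes, which are not independent replicates, averaged 0.50 there, against 0.819 in the data (covariance 0.006 against 0.052). The shared counts were 115 and 345 without anti-control replicate 2, 88 and 429 without anti-21 replicate 1, and 98 and 404 without anti-21 replicate 2. They were 60 and 299 without untreated replicate 1 and 63 and 216 without untreated replicate 2. The untreated arrays were not divided between the comparisons, which would leave 1 in each, so part of the excess may come from sharing them. No group received the transfection reagent alone, so effects of the oligonucleotides on these genes cannot be told apart from those of the reagent or the handling.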

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

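Of the tests in this part, the fits without single arrays were planned, but their use as tests of an explanation, like the tests of the culture dishes and of the VMP1 transcripts, was chosen only after the results were seen, while the comparisons with random lists of like brightness were set beforehand.

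Probe sets outside the gene tests carried signal when tested among all 54675. Of 11721 with no symbol, control probe sets not counted, 182 were past the adjusted threshold for anti-control against untreated cells (38 higher, 144 lower) and 277 for anti-21 against untreated cells (149 higher, 128 lower). Of 1801 with several symbols, 84 (18 higher, 66 lower) and 86 (29 higher, 57 lower) were past it in the same comparisons. In limma, 0 probe sets of any kind were past it for anti-21 against anti-control, with 4822 at an unadjusted p under 0.05. The 18S ribosomal RNA probe sets of anti-21 replicate 2 lay 1.14 log2 above the higher of the untreated arrays, and the poly-A spike-in mean of anti-control replicate 2 was 6.47 against 7.27 to 7.89 on the other arrays.

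The hypoxia and glycolysis list was higher with anti-21 than with anti-control (median 0.450). A shift of bright genes left by the normalization was argued against, since 0.00% of 10000 random lists of like brightness reached even a median of 50% of that size, the highest being 0.080. The array of anti-control replicate 2 did not carry the whole difference, as the median was 0.272 without it. This rests on 1 remaining anti-control array, so it says nothing of the spread between dishes. With all arrays the list had an adjusted p = 0.522 with camera at an estimated correlation (0.480). That test also takes its 3 degrees of freedom from the residuals, so the lost call cannot be put on the correlation alone. Dishes that differed in oxygen or density apart from the oligonucleotide could give the same picture and cannot be told apart from the blocking of miR-21, as the closest arrays of the groups were 0.31 apart in the list mean, against 0.24 between the anti-control arrays and 0.06 between the anti-21 arrays, with 2 dishes per group. The blocking of miR-21 itself stays open and untested.

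Of 84 reported miR-21 targets 0 were past the threshold between the oligonucleotides. Camera with an estimated correlation (adjusted p = 0.522) and fry (adjusted p = 0.318) did not call the list. As a list these targets were higher with anti-21 than with anti-control by a median of 0.057. Only 1.83% of random lists of like brightness reached 50% of that, which argues against a shift of bright or dim genes left by the normalization. The array of anti-control replicate 2 stays open as a source: without it the median was 0.040 and the adjusted p 0.240. The median also moved to 0.051 without anti-21 replicate 2, 0.031 without anti-21 replicate 1 and 0.025 with the mean of all probe sets. Against untreated cells it was -0.041 with anti-control (camera at the preset correlation, adjusted p = 0.0182) and 0.016 with anti-21 (0.555). With anti-21 the list was thus not raised above untreated cells. Release of these messages from miR-21 may account for the difference too, but cannot be told apart from a fall particular to the control oligonucleotide. Both stay open and untested.

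Of the 4 probe sets of VMP1, 3 of them shared with MIR21, anti-21 minus anti-control was 1.30 ± 0.23 for the one of VMP1 alone and 0.69 ± 0.12, 0.68 ± 0.18 and 0.02 ± 0.09 for the others, none past the threshold. The array of anti-21 replicate 2, with high 18S signals, did not carry the whole VMP1 difference, which was 0.86 without it. That fit leaves 1 anti-21 array, so the spread of the group no longer enters the error. The test thus cannot exclude that array as a main source. An equal change of every transcript annotated to VMP1 or MIR21 was argued against by the brightest shared probe set, at 0.02 ± 0.09, though whether it reads the VMP1 message or the primary transcript of miR-21 is not known. Against untreated cells the shared probe set of middle brightness was at -0.63 with anti-control (adjusted p = 0.0341 among all probe sets) and at 0.06 with anti-21. The dimmest was at -0.54 and 0.13, and that of VMP1 alone at -0.81 and 0.49. Much of the difference between the oligonucleotides is thus a fall with anti-control. An effect of blocking miR-21 on some of these transcripts stays open, and so does an effect particular to the control oligonucleotide. The arrays do not measure mature miR-21.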

How the results depend on the processing

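The assignment of probe sets shared with small RNA genes, the block with exchanged numbers and the fit without both unusual arrays were chosen after the data were seen, and the other settings were planned. For anti-21 against anti-control (19 genes) the count was 56 with an intensity trend, 9 with the mean of all probe sets, and 0 in limma with only the groups compared (1528 at an unadjusted p under 0.05), with every probe set tested (2958) and without both unusual arrays (1786). Without both unusual arrays the counts against untreated cells were 330 for anti-control and 693 for anti-21. With an estimated correlation camera called 0 lists in each of the 3 comparisons, and fry called 0, 10 and 8. Of the 13 lists called at the preset correlation for anti-control against untreated, fry did not call hypoxia, mitosis and miRNA pathway. Of the 12 for anti-21 against untreated, it did not call miRNA pathway, immediate early, mitosis, heat shock and histones. It did call the ribosomal list there, which camera did not. Genes higher with both oligonucleotides numbered 287 with dim genes left out. Leaving out each array in turn gave 0 to 15 genes between the oligonucleotides, 420 to 1516 for anti-control against untreated, 449 to 1504 for anti-21 against untreated, and 60 to 132 and 216 to 661 shared rises and falls. A group left with a lone array was assumed to vary like the others. For an array outside the comparison such a fit equals that of only the 2 groups compared (0, 1314 and 1504 genes in the order above), as a lone array adds nothing to the estimate of spread. Without an array of the comparison itself anti-21 against untreated had 449 to 737. Small differences between the oligonucleotides turned sign for RECK (0.04 with the mean of probe sets, 0.14 with every probe set, 0.16 without both unusual arrays, and -0.31 to 0.19 without each array), SERPINB5 (-0.04 with the mean, -0.15 with every probe set, and -0.03 to 0.18 without each array) and TPM1 (0.03 without probe sets marked as shared, and -0.38 to 0.01 without each array). They also did for SPRY2 (-0.12 to 0.01 without each array) and PDCD4 (0.40 with the host gene assignment, and -0.24 to 0.06 without each array, 0.03 without anti-21 replicate 1). SELENOP turned against untreated cells without probe sets marked as shared (0.16 with anti-control and 0.05 with anti-21), and so did TNRC6C with the mean of its probe sets (0.05 with anti-control). Beyond the settings that leave out arrays or test more probe sets, the cause was not tested. With the replicate number as a block the counts were 24, 1264 and 1227, and 21, 1664 and 1558 with the anti-control numbers exchanged. The fit without a block had been fixed beforehand. Deviations of equally numbered arrays correlated across genes at -0.107, 0.008 and -0.080, which gives no sign that the numbers pair the arrays. VMP1 between the oligonucleotides was past the threshold with an intensity trend (adjusted p = 0.0319) and with the block (0.0293). With the trend so were LRRFIP1 (0.0429), AGO4 (0.0387), PLK2 (0.0129), IFITM1 (0.0331) and DDIT4 (0.0129), and with dim genes left out AGO4 (0.0439) and PLK2 (0.0332). Of 2701 values of named genes under all settings, 2425 kept direction and side of the threshold, 242 lost the call, 18 gained one and 16 turned sign. Of 522 list values 473 kept their call and 49 lost it, and of 314 counts 223 stayed within 1.5 times. Centring on array medians moved the median difference of all genes by less than 0.1, and no list past the threshold changed its median's sign under the 3 scalings. List tests were not run with the robust fit or with every probe set, and the seed-match test, 8mer sites included, was not run. Signal over background limits CXCL8 and the other genes under 5.61.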

Other observations

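None of the tests in this part was chosen after the result was seen. Genes of p53 and of cell death moved in both directions once cells were transfected. Of 32 p53 targets, 5 rose and 4 fell with anti-control against untreated cells (7 and 6 adjusted over the list alone), the cell cycle inhibitor gene CDKN1A by 0.89 ± 0.09 log2 (SE, n = 2 each) and GADD45A by 0.86 ± 0.11, while TP53INP1 was at -1.11 ± 0.12. With anti-21 2 rose and 3 fell (4 and 5 adjusted over the list alone), and neither list was past the threshold (adjusted p = 0.510 and 0.651). Of 34 apoptosis regulators 2 rose and 4 fell with anti-control and 1 rose and 4 fell with anti-21 (4 and 5, and 1 and 4 adjusted over the list alone; adjusted p = 0.743 and 0.877). The BH3-only gene BIK was at -1.13 ± 0.09 and -1.24 ± 0.09 in these comparisons. The signs of the apoptosis list's median (0.014 and 0.050) and of its mean (-0.038 and -0.042) differed, with the test on the side of the mean.

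NF-kappaB and inflammatory genes had 2 rises of 26 with each oligonucleotide against untreated cells (2, and 3 with 1 fall adjusted over the list alone; adjusted p = 0.205 and 0.326), CXCL8 among those with anti-control. Immediate early genes had 1 rise and 1 fall of 27 with anti-control (4 and 1 adjusted over the list alone; adjusted p = 0.229), MYC being the fall at -0.63 ± 0.09. Of 43 DNA replication genes 0 rose and 1 fell with anti-control and 1 rose and 2 fell with anti-21 (0 and 0, then 1 and 2 adjusted over the list alone; adjusted p = 0.298 and 0.464). Cholesterol genes (1 rise of 27 each, also adjusted over the list alone; adjusted p = 0.947 and 0.783) and lysosome genes (1 rise of 29, then 1 fall; 0 and 1 adjusted over the list alone; adjusted p = 0.827 and 0.305) were not past the threshold, nor were ribosomal protein genes with anti-21 (1 fall of 20, also adjusted over the list alone; adjusted p = 0.116). Markers of other cells showed no member past the threshold in any comparison: mesenchymal, fibroblast and basal markers had medians of 0.077 and 0.059 (24 genes, adjusted p = 0.390 and 0.384) and blood and endothelial markers 0.028 and 0.083 (16 genes, adjusted p = 0.459 and 0.201). Between the oligonucleotides the median, mean and test of a list differed in sign for the miRNA pathway, luminal, mesenchymal, DNA replication and apoptosis lists, all with an adjusted p of at least 0.871. Against untreated cells they also differed for the cholesterol list with both oligonucleotides and the lysosome list with anti-control. Between the oligonucleotides AGO4 (0.67 ± 0.11, adjusted p = 0.0754), PLK2 (-0.61 ± 0.09, 0.0685), EGR1 (0.74 ± 0.21, and 0.36 to 1.13 without each array), IFITM1 (0.53 ± 0.10) and DDIT4 (0.55 ± 0.10) were among the members with the smallest p in these and other lists, none past the threshold.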
